A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 36 samples.

How the data were processed

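RNA from 2 rel-negative strains of *Synechococcus elongatus* (relA+ and relAE335Q) was sequenced by the submitters at dusk and at 8 times in darkness, with 2 replicates per strain and time, giving 36 libraries in 18 groups. Per the labels, cells grew in BG11 medium at 30 °C under 40 µE of light, went through 2 cycles of 12 h light and 12 h dark, and external RNA standards were added at lysis. Ribosomal RNA was depleted with Ribo-Zero, strand-specific TruSeq libraries were made, and an Illumina HiSeq instrument was used. The submitters' processing notes list Bowtie 0.12.7. The genome build, the annotation version and the counting rule were not given in the sources used here. The column headers of the table write spoT- where the sample labels write rel-, and columns were matched to samples by relA allele, time and replicate number. All columns of values were used.

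The values are the signal deposited by the authors. In every library each value was a whole multiple of one step, within a tolerance of 0.001, for 100% of the values, so the signal equals read numbers times one factor per library. In 13 libraries the step was checked against at least 100 low values, and in the others it was the greatest common step of all values. The value of one read lay between 1.38 and 23.2. No source used here states what the factor is, and no gene length enters the values. Reads per library recovered in this way ran from 1.77 M (M stands for mega; relAE335Q dark 2 h replicate 2) to 16.7 M. Replicate pairs differed by more than counting error, with a chi-square per degree of freedom between 74.9 and 245, and correlated across loci with a Pearson r of log2 values between 0.952 and 0.974.

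None of the locus tags was found among the 2785 genes of the reference table (0 matches), and the table of values carries no gene names. The gene lists, the pairing of named loci with tags, the contrasts, the tests and the first set of alternatives below were fixed before the data were examined. Of 22 gene lists, 4 had loci written down and 18 could not be filled from symbols or products. The 18 lists cover ribosomal proteins, translation factors, RNA polymerase and sigma factors, ATP synthase, both photosystems, phycobilisomes, electron carriers, pigment synthesis, respiration, chaperones, nitrogen assimilation, cell division, pili, high light proteins, rRNA and tRNA, and external standards, and they were not analysed here. The 18 named loci were paired with their tags from general knowledge of this strain, and nothing in the files checks the pairing. The lists hold hpf alone, 7 clock genes, 2 Rubisco genes of the carbon fixation list and 7 genes of glycogen breakdown and the pentose phosphate pathway. Named loci were rel, hpf, kaiA, kaiB, kaiC, rpaA, rpaB, gnd, zwf and rbcL in every contrast, and up to 4 members of each list with the largest absolute moderated t in that contrast. The part of the rule that takes the largest changes among loci with a symbol or product gave none. Outside the rule, the values of cikA and sasA, of list members beyond those 4 and of the single times of gnd, opcA, zwf, glgP and gap1 are given, and these and Synpcc7942_1661, Synpcc7942_0195, Synpcc7942_1488 and Synpcc7942_1439 were chosen after their values were seen. The psbA genes could not be located and were not analysed here.

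Loci with at least 10 recovered reads in at least 2 libraries were tested, which kept 2699 and removed 16. Signal was transformed as log2(value + 10). One mean per group was fitted over all 36 libraries with limma 3.58.1 with a mean-variance trend, in R 4.3.3, leaving 18 residual degrees of freedom. The choice between limma and a count test had been tied to the unit, and since the values are scaled by an unstated factor, limma was used. Contrasts were late dark (equally weighted mean of 1, 2, 4, 8 and 12 h) against dusk in each strain, relA+ minus relAE335Q at dusk and in late dark, the difference of the late dark responses, each single time, and F tests over the 8 dark times. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast, and members were also adjusted over the list alone. On the deposited scale 9 of 15 list results passed with the preset correlation and none of these with an estimated one. Whether replicate numbers pair the libraries of a strain was checked from the deviations of log2 values from group means, correlated across loci between times. In relA+ the 36 pairs of times correlated at 0.281 to 0.789, all above 0.1, and the fit with the replicate number as a block is given beside the relA+ results it changes. In relAE335Q (0.0767 to 0.788) and between strains (-0.0696 to 0.471) not all pairs did. The medians were 0.463 in relA+, 0.413 in relAE335Q and 0.222 between strains, so the lowest pairs set relAE335Q apart from relA+, not the median. A correlation across loci cannot see a shift of a whole library, and the check gave the same values on both scales. Such a shift was present in every group of both strains. The median log2 of replicate 2 minus replicate 1 lay between 0.151 and 1.09. Outside relA+ the block is given among the other settings and for the difference of the responses. Judging each strain by itself was decided after the calls of both fits had been seen. Totals of 2 against 2 libraries were compared by exact permutation tests.

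The first set of alternatives was pseudocounts of 1 and 100, no filter, median centring, quantile normalization, limma without trend, only the libraries of the contrast, a replicate block, library weights, a log2 change of at least 1, and leaving out each time course and each dusk library. Chosen after seeing the data were edgeR 4.0.16 quasi-likelihood tests on the recovered reads (with the deposited scale and with TMM), values scaled to a common total without the R series, median centring with the replicate block, leaving out the library with the fewest reads, 1 value per time course on both scales, and the R and B series as lists. DESeq2 and its size factors were not run, since the table does not hold counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

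The tests were checked on simulated data with the group sizes and the factor per library of this study, and 200 changed loci. The dispersion was 0.0874, estimated after TMM. Every library was given the same mean signal before the changes, so simulated depths were not the real ones. Differences in total signal between replicates were absent too, so the shares below may not describe the tests on the deposited scale. At a log2 change of 1, limma recovered 43.3% of changed loci in relA+ late dark, 44.8% in relAE335Q late dark, 17.9% at dusk, 94% for the strains in late dark and 13.4% for the difference of responses. At a log2 change of 2 it recovered 98.5%, 100%, 85.1%, 100% and 89.6%. Between 4.68% and 8% of calls in these contrasts were false, and no recovered locus had the wrong sign. Libraries were simulated as independent, without a deviation shared by a time course, so these shares may not carry over to the real libraries, where splitting the late dark libraries by replicate number called 364 loci on the deposited scale and 76 median centred. Smaller differences at dusk and between responses were often not detectable even so with 2 libraries per group.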

Results

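RNA levels were measured by sequencing in 36 libraries of the cyanobacterium *Synechococcus elongatus*, from 2 strains sampled at dusk and after 5, 15 and 30 min and 1, 2, 4, 8 and 12 h of darkness. Per the labels both strains lack rel, and one carries relA+ while the other carries relAE335Q. In bacteria, genes of the rel and relA family make the alarmone ppGpp. Each of the 18 groups of strain and time held 2 libraries, which the labels number as replicates 1 and 2. Libraries of the same strain and number are called a time course here, though no label says that they share a culture. The table lists 2715 loci, of which 53 have tags of an R series and 50 have tags of a B series. A library held between 1.77 and 16.7 M recovered reads, with a median of 5.82 M (M stands for mega). The unit is the deposited signal, which equals whole reads times one factor per library, and what the factor stands for was not given in the sources used here. Per the labels external RNA standards were added at lysis, but whether the factor rests on them was not stated. Changes are log2 differences of group means, with the standard error of the limma fit, and each is given on the deposited scale and, where it differs in sign or call, relative to the median of all loci in each library (median centred). P-values measure only the spread between these libraries, which may be technical, since nothing in the labels says that replicates came from separate cultures.

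The rel locus (Synpcc7942_1377), which the labels give as absent from both strains, had between 0 and 39 reads per library, with a median of 6.5. It ranked at or below percentile 6.63 of the loci in every library. The relA transgene was not analysed here.

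The first comparison asks how much signal the libraries of each strain held as darkness went on. Summed signal at dusk was 19.2 ± 5.755 M in relA+ and 48.3 ± 12.3 M in relAE335Q (mean ± SD, n = 2 libraries each), a ratio of 2.515 (exact permutation test, two-sided, p = 0.333, the smallest p that this design allows). At 2 h the means were 17.6 ± 4.17 and 33.1 ± 11.3 M (n = 2 each). At 12 h they were 13.6 ± 5.015 and 14.2 ± 6.93 M (n = 2 each, exact permutation p = 1). The total at 12 h was 0.703 ± 0.0505 of the dusk total in relA+ and 0.284 ± 0.0713 of it in relAE335Q (n = 2 time courses each, exact permutation p = 0.333). Replicate 2 had between 1.1997 and 2.30 times the total of replicate 1 within each group. The R series held 15.2% and 15.5% of the signal at dusk in the relA+ libraries and 30.1% and 27.96% at 12 h. In relAE335Q it held 12.7% and 19.5% at dusk and 37.3% and 35.6% at 12 h. The median log2 change of all loci was not near 0 on the deposited scale. It was -0.77 in late dark (the equally weighted mean of 1, 2, 4, 8 and 12 h) against dusk in relA+, -1.44 in relAE335Q, -1.37 for relA+ minus relAE335Q at dusk, -0.69 for the same difference in late dark and 0.64 for the difference between the responses.

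**Figure D1:**
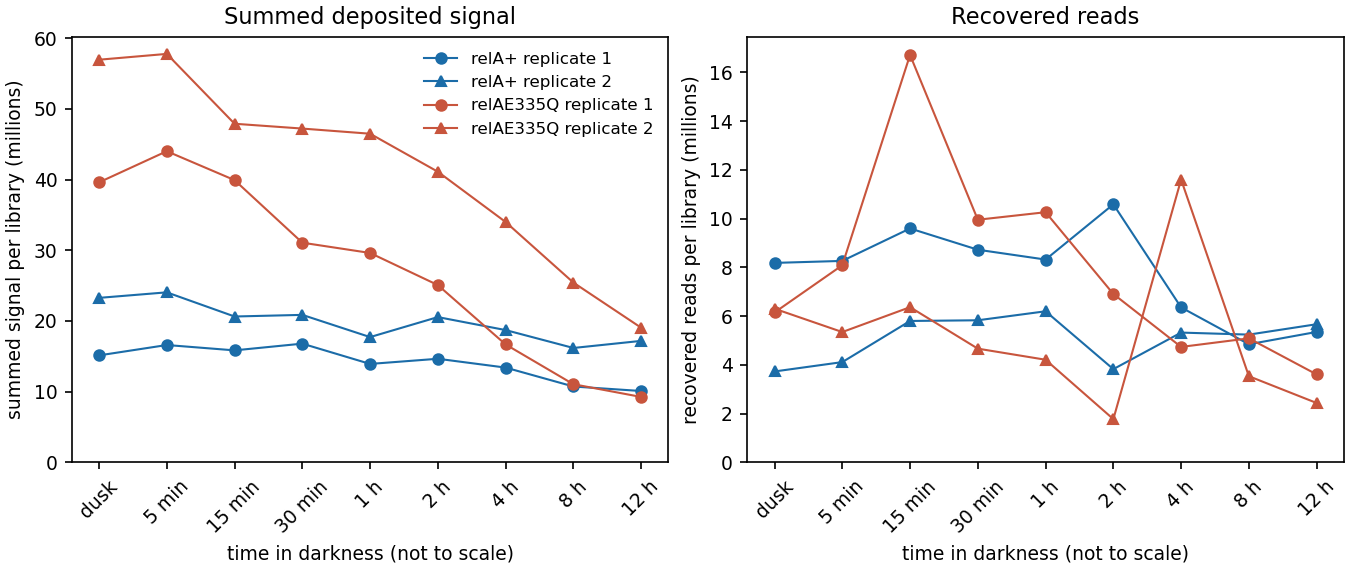
Summed deposited signal of each library in M (vertical axis) against time in darkness (horizontal axis) for the 4 time courses, with points for libraries and lines for time courses. At dusk the relAE335Q totals were 39.6 and 57.0 M and the relA+ totals 15.1 and 23.3 M, and at 12 h they were 9.25 and 19.05 against 10.1 and 17.2 M.

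The second comparison asks what darkness did to RNA levels in relA+. The gene hpf (Synpcc7942_2352), whose product holds idle ribosomes in an inactive form, rose in late dark by 3.78 on the log2 scale (SE 0.648, 13.7-fold, adjusted p = 4.86e-05) and lay above the dusk mean in 10 of 10 late libraries. Its signal was 6970 ± 78.7 at dusk and 98544 ± 24562 at 12 h (mean ± SD, n = 2 each). The genes for the large and small subunits of Rubisco, the enzyme that fixes carbon dioxide, fell: rbcL (Synpcc7942_1426) changed by -3.84 (adjusted p = 6.23e-09) and rbcS (Synpcc7942_1427) by -4.16 (adjusted p = 4.49e-09). The mean signal of rbcL was 75578 ± 14134 at dusk, 8936 ± 1460 at 1 h and 4859 ± 2798 at 12 h (n = 2 each). Of 7 genes of the circadian clock and its output, 6 fell, and 6 passed when adjusted over the list alone. Among all loci 1092 of 2699 passed as lower. The oscillator genes kaiA (Synpcc7942_1218), kaiB (Synpcc7942_1217) and kaiC (Synpcc7942_1216) changed by -2.59, -2.62 and -2.47, and each lay below its dusk mean in 10 of 10 late libraries. The response regulator genes rpaA (Synpcc7942_0095) and rpaB (Synpcc7942_1453) changed by -2.29 and -2.58. These falls of the kai, rpa and rbc genes passed on both scales. The kinase gene sasA (Synpcc7942_2114) fell by 0.99 (adjusted p = 0.0369), a call lost after median centring (-0.20, adjusted p = 0.307). It was also lost without relA+ replicate 1 or 2 and without either relA+ dusk library. The kinase gene cikA (Synpcc7942_0644) was at 0.67 (adjusted p = 0.193, or 0.00769 with the replicate number as a block), and it rose relative to the median of all loci (1.47, adjusted p = 2.94e-05).

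Across the 2699 loci tested, 1257 passed in relA+ late dark, 165 higher and 1092 lower, and after median centring 1446 passed, 720 higher and 726 lower. The count was 455 without relA+ dusk replicate 2, 610 without relA+ replicate 1 and 585 without relA+ replicate 2. With the replicate number as a block 1868 loci passed in relA+ late dark on the deposited scale, 326 higher and 1542 lower. Among loci above the lower quartile of mean level with the same direction in both replicates, Synpcc7942_1661 and Synpcc7942_0195 had the largest rises (4.60 and 4.27), and Synpcc7942_1488 and Synpcc7942_1439 the largest falls (-6.70 and -6.59). Over the 8 dark times together, 1036 loci changed in relA+ (178 without replicate 1, 408 without replicate 2 and 1973 with the replicate number as a block), and 1492 changed after median centring. Against the other loci, the clock list (median -2.47, camera adjusted p = 0.0175, adjusted p = 0.434 with an estimated correlation) and the 2 Rubisco genes (median -4.00, camera adjusted p = 0.00443, adjusted p = 0.0763 with an estimated correlation) lay lower in relA+ late dark. After median centring both list results held with an estimated correlation (adjusted p = 0.0264 for each list).

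Of 7 genes of glycogen breakdown and the oxidative pentose phosphate pathway (the sugar list), 0 passed in relA+ late dark on the deposited scale, over all loci or adjusted over the list alone (limma, 0 at an unadjusted p under 0.05; edgeR on recovered reads, 0). With the replicate number as a block, 4 of the 7 passed, gnd, opcA and zwf as lower (adjusted p = 0.000248, 0.000343 and 0.00626) and gap1 as higher (adjusted p = 0.0329), and 3 lower and 1 higher passed when adjusted over the list alone. The list had a median of -0.21 and a mean of -0.18, and camera, with the direction up, did not pass (adjusted p = 0.173, adjusted p = 0.588 with an estimated correlation). The values ran from -0.98 for gnd (Synpcc7942_0039), for a dehydrogenase of the pentose phosphate pathway, to 0.54 for gap1 (Synpcc7942_0245), for a glyceraldehyde phosphate dehydrogenase of glycolysis. The genes zwf (Synpcc7942_2334), for the first enzyme of the pathway, and opcA (Synpcc7942_2333), for its activator, were at -0.60 and -0.81. After median centring, without the block, gnd was at -0.19 (adjusted p = 0.703) and opcA at -0.02 (adjusted p = 0.959). There zwf turned to 0.19 (adjusted p = 0.726). These median centred values differ from the lower calls of the block in both scale and block, so they cannot say which of the 2 matters. The single times of this list were chosen for description after the values were seen. At 2 h the glycogen phosphorylase gene glgP (Synpcc7942_0244) and gap1 rose relative to the median of all loci (2.09, adjusted p = 0.00238, and 2.32, adjusted p = 0.00203), while on the deposited scale they were at 1.68 (adjusted p = 0.0796) and 1.92 (adjusted p = 0.0791). At 12 h, gnd and opcA had fallen on both scales (-3.03 and -2.92 deposited, -1.74 and -1.63 median centred). At the same time zwf fell on the deposited scale (-2.56, adjusted p = 0.00718) but did not pass after median centring (-1.28, adjusted p = 0.058). The signal of glgP was 16106 ± 1853 at dusk, 51612 ± 100 at 2 h and 6550 ± 1382 at 12 h (mean ± SD, n = 2 each). After median centring tal (Synpcc7942_2297), glgP and gap1 passed as higher in relA+ late dark (1.16, 1.24 and 1.34). On the deposited scale they were at 0.36, 0.45 and 0.54 and did not pass without the block.

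The third comparison asks the same of relAE335Q. There hpf rose in late dark by 1.65 (SE 0.648, 3.13-fold, adjusted p = 0.0263) and lay above the dusk mean in 9 of 10 late libraries. This call was lost in 6 of 24 settings run, among them leaving out relAE335Q replicate 2, relAE335Q dusk replicate 2, relA+ replicate 1 or relA+ replicate 2, with a log2 change between 0.0081 and 3.29 and an adjusted p between 1.15e-06 and 0.991 over those 24. Its signal was 18835 ± 11402 at dusk, 101003 ± 54753 at 30 min and 44360 ± 39836 at 12 h (mean ± SD, n = 2 each). Of the clock genes, 6 of 7 fell (1813 of all 2699 loci tested passed as lower), and 6 passed when adjusted over the list alone. The falls were -3.58 for kaiA, -3.69 for kaiB, -2.81 for kaiC, -3.33 for rpaA and -3.40 for rpaB, each in 10 of 10 late libraries and on both scales. The sixth was sasA, which fell by 1.45 (adjusted p = 0.00194) but was at -0.03 after median centring and did not pass without relAE335Q dusk replicate 2. The remaining member, cikA, was at -0.06 on the deposited scale (adjusted p = 0.9) and rose after median centring (1.35, adjusted p = 6.4e-05), so its direction turned with the scale. Both Rubisco genes fell (rbcL by 2.91 and rbcS by 3.56), in 10 of 10 late libraries each. The mean signal of rbcL was 81306 ± 16951 at dusk, 30171 ± 2678 at 1 h and 4232 ± 609 at 12 h (n = 2 each).

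Of the 7 genes of glycogen breakdown and the pentose phosphate pathway, gnd fell in relAE335Q late dark (-1.48, adjusted p = 0.0152), and 0 passed when adjusted over the list alone (limma, 1 at an unadjusted p under 0.05; edgeR, 1). The gnd call was lost after median centring (-0.06, adjusted p = 0.899) and without relAE335Q dusk replicate 2, relA+ replicate 1 or relA+ replicate 2 (adjusted p between 5.51e-07 and 0.95 over 24 settings). The list had a median of 0.02 and a mean of -0.18, and camera placed it above the other loci (adjusted p = 0.0131, adjusted p = 0.286 with an estimated correlation). After median centring 5 members passed as higher, among them fbp (Synpcc7942_2335), for a sugar bisphosphatase (2.36, adjusted p = 1.75e-05), gap1 (1.78) and glgP (1.67). On the deposited scale fbp, gap1 and glgP were at 0.94, 0.36 and 0.25 and did not pass. Another of the 5 was zwf (1.435, adjusted p = 0.00645), which was at 0.02 on the deposited scale and did not pass there. After median centring opcA also passed as higher (1.09), where the deposited scale had it at -0.33 (adjusted p = 0.53), so its direction turned with the scale. The pentose phosphate gene tal was at -1.03 (adjusted p = 0.119).

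Across all tested loci, 1904 passed in relAE335Q late dark, 91 higher and 1813 lower, and after median centring 1555 passed, 736 higher and 819 lower. The count was 1195 without relAE335Q dusk replicate 2. By the same criteria Synpcc7942_0195 (3.62) had the largest rise and Synpcc7942_1488 (-7.69) the largest fall. Over the 8 dark times, 2204 loci changed, and 1636 after median centring. The clock list (median -3.33, camera adjusted p = 0.0166) and the Rubisco pair (median -3.24, camera adjusted p = 0.0306) lay below the other loci, both with adjusted p = 0.286 with an estimated correlation. After median centring the adjusted p with an estimated correlation was 0.0424 for the clock list and 0.117 for the Rubisco pair.

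**Figure D2:**
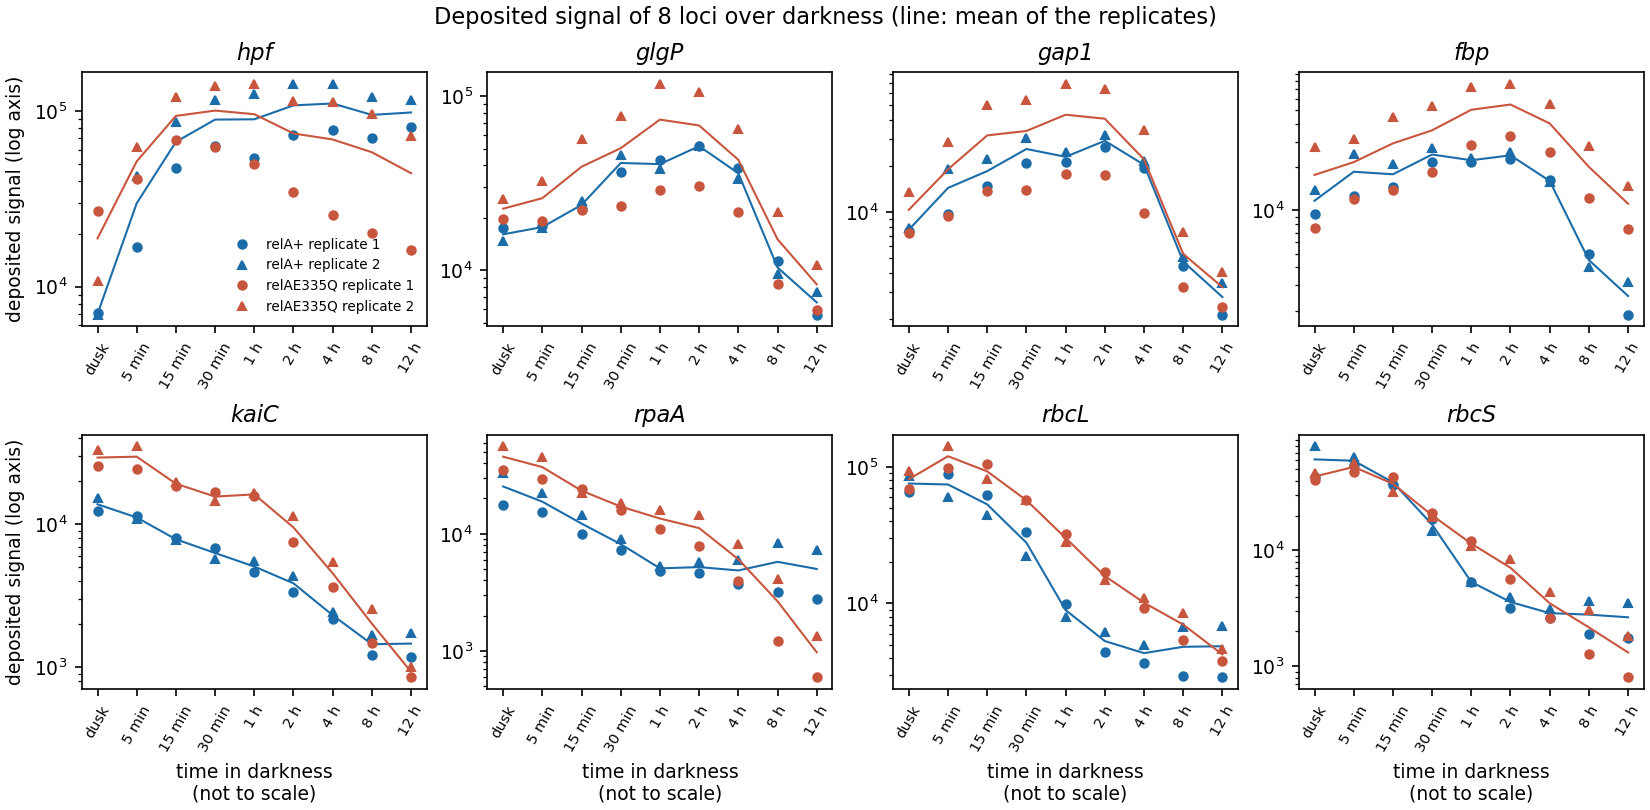
Deposited signal on a log axis (vertical) against time in darkness (horizontal) for named loci in both strains, with points for libraries and lines for group means of 2 libraries. The mean of hpf went from 6970 at dusk to 98544 at 12 h in relA+ and from 18835 to 44360 in relAE335Q, and that of kaiC from 13815 to 1468 and from 29300 to 932.

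Single times against dusk show when loci passed the test in each strain. On the deposited scale the counts in relA+ were 4, 42, 215, 553, 493, 696, 1176 and 1407 from 5 min to 12 h. In relAE335Q they were 0 (limma, 32 at an unadjusted p under 0.05; edgeR was not run at single times), 7, 96, 243, 563, 1267, 2009 and 2292. After median centring the counts were 21, 205, 662, 906, 1035, 1191, 1307 and 1352 in relA+ and 12, 108, 266, 648, 989, 1256, 1489 and 1586 in relAE335Q. In relA+, hpf had risen at 15 min (3.20, adjusted p = 0.0477). In relAE335Q hpf passed at no single time on the deposited scale, and from 15 min on it passed after median centring.

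The fourth comparison asks how far the strains' late dark responses covered the same loci. No library is shared between these contrasts. Across the 2699 loci the log2 changes had a Pearson r of 0.778 and a Spearman rho of 0.755, where loci are not independent replicates. After median centring 515 loci were higher in both strains, where independent lists of those sizes would share 196, and 530 were lower in both (220 for independent lists). There were 19 loci higher in relA+ and lower in relAE335Q, and 7 the other way round. As deposited, 73 loci were higher in both (5.56 for independent lists) and 1040 lower in both (734 for independent lists), with 10 higher in relA+ and lower in relAE335Q and 1 the other way round. The kai genes, rpaA, rpaB, rbcL and rbcS were among those lower in both strains on both scales, and hpf was higher in both.

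**Figure D3:**
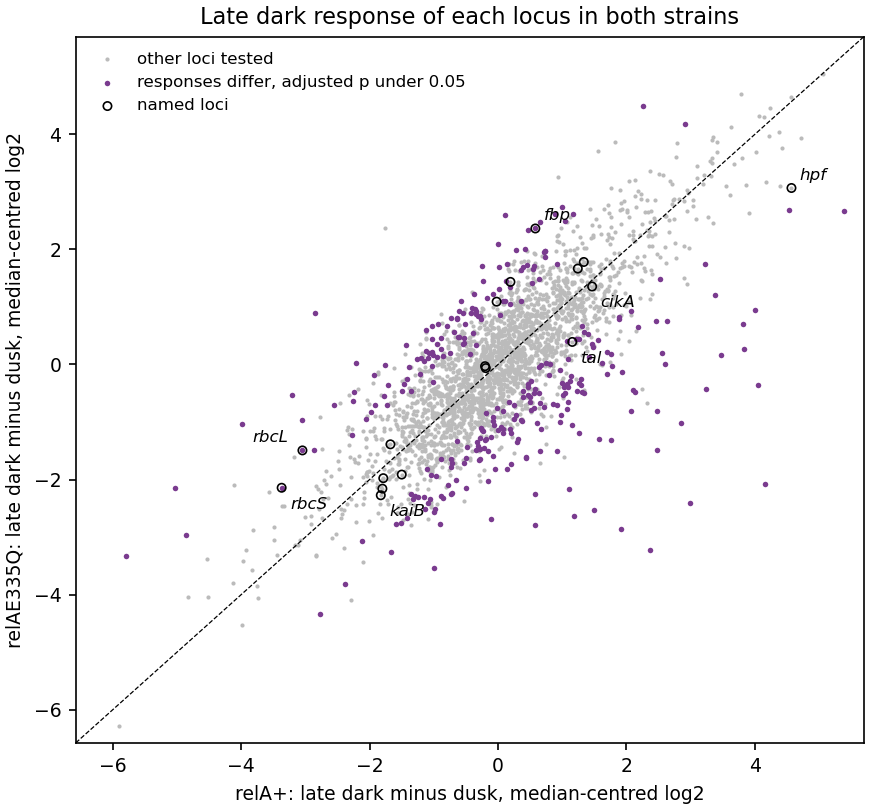
Median centred log2 change in late dark against dusk in relAE335Q (vertical) against that in relA+ (horizontal), with a point for each of the 2699 loci tested and the named loci marked. Purple points are loci whose responses differed after median centring (limma, adjusted p under 0.05). The Pearson r across loci was 0.778, and the kai, rpa and rbc genes lie in the lower left with hpf in the upper right.

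The fifth comparison asks how the strains differed before darkness. At dusk on the deposited scale 4 of the 7 clock genes were lower in relA+ than in relAE335Q, and 4 passed when adjusted over the list alone. These were kaiA (-2.15, SE 0.378, adjusted p = 0.000531), kaiB (-1.38, adjusted p = 0.0239), kaiC (-1.08, adjusted p = 0.0219) and sasA (-1.33, adjusted p = 0.0301), each lower in 4 of 4 pairs of libraries. The genes hpf, rpaA, rpaB, cikA, gnd, tal and glgP were also lower in 4 of 4 pairs but did not pass. Both relAE335Q totals lay above both relA+ totals, so this count says little about a single locus. Across all loci 1520 of 2699 passed as lower. None of the 4 clock genes called passed after median centring, where kaiA was at -0.79 and kaiB at -0.02, and kaiC (0.29) and sasA (0.04) turned direction. The calls of kaiB, kaiC and sasA were also lost without relA+ replicate 1, relAE335Q replicate 2, relA+ dusk replicate 1 or relAE335Q dusk replicate 2, those of kaiC and sasA also without relA+ replicate 2, and that of sasA also without relA+ dusk replicate 2. The Rubisco genes did not pass on the deposited scale (rbcL -0.10, adjusted p = 0.833; rbcS 0.43, adjusted p = 0.407; limma, 0 of 2 at an unadjusted p under 0.05; edgeR 0). After median centring both were higher in relA+ (rbcL 1.27, adjusted p = 0.0474, a turn in direction; rbcS 1.80, adjusted p = 9.86e-05). The call of rbcL was lost on the other relative scales and with 1 value per time course (adjusted p between 0.0643 and 0.166), where that of rbcS was kept. Of the 7 genes of glycogen breakdown and the pentose phosphate pathway 0 passed on either scale, over all loci or adjusted over the list alone (limma, 0 at an unadjusted p under 0.05 as deposited and 2 median centred; edgeR 0), with gnd at -1.08, tal at -0.82 and glgP at -0.48. The gene hpf was at -1.29 (adjusted p = 0.166), with 0.08 after median centring.

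Across all tested loci, 1536 passed at dusk, 16 higher and 1520 lower in relA+, against 94 after median centring, 68 higher and 26 lower. The deposited count was 150 without relA+ replicate 1, 235 without relA+ dusk replicate 1, 229 without relAE335Q replicate 2 and 145 without relAE335Q dusk replicate 2. Camera placed the Rubisco pair (median 0.16, adjusted p = 0.00146, adjusted p = 0.0632 with an estimated correlation) above the other loci. It did the same for the sugar list, whose median of -0.43 and mean of -0.56 have the other sign (adjusted p = 0.00146, adjusted p = 0.277 with an estimated correlation). After median centring the adjusted p with an estimated correlation was 0.0134 for the Rubisco pair and 0.384 for the sugar list. The clock list gave an adjusted p of 0.72.

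The sixth comparison asks how the strains differed in late dark. On the deposited scale 3 of the 7 clock genes were lower in relA+, and 3 passed when adjusted over the list alone. These were kaiA (-1.17, SE 0.169, adjusted p = 1.86e-06, lower in 16 of 20 pairs of libraries of the same time), kaiC (-0.74, adjusted p = 0.000458) and sasA (-0.87, adjusted p = 0.00151). After median centring kaiA stayed lower (-0.43, adjusted p = 0.00584), kaiC was at -0.0012 and sasA at -0.13. On that scale rpaA (0.90), cikA (0.77), rpaB (0.55) and kaiB (0.43) were higher in relA+, and of these rpaB (-0.19) and kaiB (-0.31) had the other sign on the deposited scale. There rpaA was at 0.16 and cikA at 0.03, and neither passed. Of the Rubisco genes 1 of 2 was lower in relA+, rbcL (-1.03, adjusted p = 0.000101), which was at -0.29 after median centring (adjusted p = 0.116). The other, rbcS, was at -0.17 and turned to 0.57 (adjusted p = 0.000183) after median centring. In the sugar list 3 of 7 were lower in relA+, and 3 when adjusted over the list alone: fbp (-1.49, adjusted p = 0.000193, lower in 20 of 20 pairs), opcA (-0.88, adjusted p = 0.00552) and zwf (-1.05, adjusted p = 0.0102). The tags of these 3 genes follow each other, and changes of neighbouring tags were correlated, so they may not be independent. Across all loci 1446 of 2699 passed as lower. After median centring fbp stayed lower (-0.75, adjusted p = 0.00498), tal was higher (1.31, adjusted p = 1.18e-05), and opcA and zwf did not pass. On the deposited scale tal was at 0.57 and did not pass. Without relA+ replicate 1 the calls of kaiC, sasA, opcA and zwf were lost, without relAE335Q replicate 2 those of sasA, opcA and zwf, and without relA+ replicate 2 those of opcA and zwf. The gene hpf was at 0.84 (adjusted p = 0.0555; its list holds hpf alone, so that adjusting over the list alone, where it passed, is no adjustment), and it was higher in relA+ after median centring (1.58, adjusted p = 3.55e-05).

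Across all tested loci, 1708 passed in late dark after median centring, 923 higher and 785 lower in relA+. The larger side turned on the other relative scales. Quantile normalization gave 832 higher and 852 lower, edgeR with TMM 827 and 913, and scaling to a common total without the R series 677 and 1005. On the deposited scale 1580 passed, 134 higher and 1446 lower. The count was 976 without relA+ replicate 1. With 1 value per time course (2 against 2) it was 162 on the deposited scale and 549 median centred, and none of kaiA, kaiC, sasA, rbcL, fbp, opcA and zwf then passed on either scale. Of the loci called after median centring, rpaA, rpaB, kaiB, cikA and rbcS also did not pass with 1 value per time course (adjusted p between 0.0508 and 0.234). In that median centred setting hpf (1.58, adjusted p = 0.0271) and tal (1.31, adjusted p = 0.0284) did pass, as higher in relA+. None of the clock list, the Rubisco pair and the sugar list lay apart from the other loci by camera (adjusted p = 0.912 for each), and the clock and sugar lists had medians of -0.31 and -0.58 where camera had the direction up. At single times the deposited counts were 1536, 1580, 1433, 1028, 1514, 976, 567, 376 and 412 from dusk to 12 h, and the median centred counts 94, 199, 202, 263, 265, 274, 547, 952 and 1080. At 12 h the 412 loci were 226 higher and 186 lower in relA+.

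The seventh comparison asks whether the late dark response itself differed between strains, tested as the difference of the responses. On the deposited scale the result depended on whether the replicate number was taken as a block, a pairing that no label gives. Replicate 2 held the higher total in every group of both strains (1.1997 to 2.30 times that of replicate 1). The fit without the block counts this shift as spread. With the block hpf (adjusted p = 0.00393), tal (0.00208), fbp (0.00412), kaiA (0.00676), kaiB (0.0122) and rpaA (0.029) passed. Without the block none of the named loci passed over all loci, which does not show that the responses were alike. The deposited values that follow are from the fit without the block. The largest values were 2.13 for hpf (SE 0.916, adjusted p = 0.212, while over its list of 1 gene it passed with no adjustment made), 1.39 for tal (adjusted p = 0.351) and -1.16 for fbp (adjusted p = 0.394). Of the clock, Rubisco and sugar lists 0 of 7, 0 of 2 and 0 of 7 passed, also when adjusted over the list alone (limma, 1, 0 and 0 at an unadjusted p under 0.05; edgeR 0, 0 and 0). After median centring rbcL (-1.55, SE 0.386, adjusted p = 0.0128), rbcS (-1.23, adjusted p = 0.0084) and fbp (-1.78, adjusted p = 0.0358) passed, each with a lower change in relA+ than in relAE335Q. On the deposited scale rbcL and rbcS were at -0.93 and -0.60 and did not pass. None of rbcL, rbcS and fbp passed with 1 value per time course and median centring (adjusted p = 0.0718, 0.0992 and 0.0882). Camera placed the Rubisco pair below the other loci (median -0.76, adjusted p = 0.00758, adjusted p = 0.098 with an estimated correlation). It also placed the sugar list below them (adjusted p = 0.0356, adjusted p = 0.558 with an estimated correlation), although that list had a median of 0.18 and a mean of 0.0020. After median centring the camera call of the sugar list was lost (adjusted p = 0.118). The clock list gave an adjusted p of 0.331 on the deposited scale.

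Across all tested loci, 40 passed in that difference, 38 with a higher and 2 with a lower change in relA+ (512 at an unadjusted p under 0.05), and after median centring 295 passed, 180 higher and 115 lower. The balance depended on the relative scale. Quantile normalization gave 175 higher and 120 lower, edgeR with TMM 137 and 161, and scaling to a common total without the R series 109 and 101. The deposited count fell to 0 without relA+ replicate 2, without relAE335Q replicate 1 and without either relAE335Q dusk library (limma, 211, 321, 566 and 199 at an unadjusted p under 0.05; edgeR was not run without these libraries), to 12 and 1 without relA+ dusk replicate 1 and 2, and was 75 without relAE335Q replicate 2. With 1 value per time course it was 436 deposited and 19 median centred, and with the replicate number as a block 972 deposited. Over all 8 dark times together 239 loci differed in response, 312 after median centring and 1532 with the block on the deposited scale. The count of 239 became 21 without relA+ replicate 1, 0 without relA+ replicate 2 (limma, 121 at an unadjusted p under 0.05), 7 without relAE335Q replicate 1 and 133 without relAE335Q replicate 2.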

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

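Each test of an explanation in this part was chosen after the result was seen.

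At dusk the deposited totals were higher in relAE335Q than in relA+, by a ratio of 2.515 (n = 2 libraries each). More reads sequenced from relAE335Q cannot be the whole cause: the ratio of mean recovered reads was 1.045, and in replicate 1 relAE335Q had 0.752 times the reads and 2.62 times the total of relA+, although in replicate 2 it had 1.69 times the reads and 2.45 times the total. A few loci holding much of the signal cannot either, since the median log2 difference over loci outside the R series was -1.375 and 96.5% of them were below 0. The total equals reads times the factor per library set by the authors, so what the reads leave over lies in that factor. What the factor stands for is open: it may be a choice of scaling or carry a true difference in RNA per cell. Per the labels external RNA standards were added at lysis, but no source used here says that the factor rests on them. Median centring takes off a shift shared by all loci in either case, so it cannot decide between them. The mean value of one read was 1.914 times as high in relAE335Q (3.48 times in replicate 1 and 1.45 times in replicate 2), and without the basis of the factor this cannot be told apart from an effect of the relA allele.

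Levels in late dark differed between the strains at 1580 loci on the deposited scale and 1708 after median centring. Libraries of the same strain and replicate number (a time course) tend to deviate together, so reassigning single libraries is no fair test, and whole courses were reassigned. That leaves 3 splits, too few for a share under 0.05; with 1 value per course the real split gave 162 loci deposited and 549 median centred, and the highest other 0 on both scales. For the median centred count total depth can be excluded as the whole cause. With each library thinned to 1774118 reads 1655 loci passed after median centring, 1618 of them shared with the 1708. Thinning was not run for the deposited count. It matched the total alone, and the share of the R series still differed between libraries.

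The late dark response differed between the strains by a test of the difference itself at 40 loci (239 loci over all dark times). After median centring it differed for rbcL (-1.553), rbcS (-1.227) and fbp (-1.782), though none of these passed with 1 value per course and median centring (adjusted p = 0.0718, 0.0992 and 0.0882). With whole courses reassigned (3 splits, too few for a share under 0.05) the real split gave 436 loci deposited and 19 median centred, and the highest other 0 on both scales. With every library thinned to the same total of reads 239 loci passed median centred, 226 of them shared with the 295 that passed at full depth. So total depth can be excluded as the whole cause of that median centred count. It was not tested for the 40 loci on the deposited scale or for the test over all dark times. A difference due to the relA allele remains a candidate explanation that 2 time courses per strain cannot separate from a difference between courses.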

How the results depend on the processing

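The settings named in the last paragraph as added were chosen after the results were seen. With pseudocounts of 1 and 100, no filter and limma without trend, all 8 counts stayed within 1.5 times their reported value and all 85 results of named loci kept direction and side of the threshold. Among those 85, calls were lost for 12 and gained for 22 with median centring, for 10 and 21 with quantile normalization, for 11 and 21 with edgeR and TMM, for 9 and 21 when scaled to a common total without the R series, for 3 and 4 with only the libraries of the contrast, for 9 and 6 with 1 value per course and for 14 and 13 with that and median centring; leaving out libraries ended at most 10 (relA+ replicate 1) and added at most 14 (relAE335Q replicate 1). Of 30 locus results past the threshold, 15 stayed past it in all settings run. The results kept in every setting were all of late dark against dusk within a strain. None of the calls between the strains, at dusk or in late dark, was kept in every setting. Small changes were often missed in simulated data with 2 libraries per group. A log2 change of 1 in the difference of responses was recovered in 13.4% of simulated loci, in libraries simulated as independent. The effect of depth was not tested there. The cause was not tested for any change below, except that leaving out libraries or taking 1 value per course leaves fewer samples; where a group is left with 1 library, it is assumed to vary like the other groups.

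Counts with libraries left out ranged from 178 (without relA+ replicate 1) to 1106 for loci changed over time in relA+, 1670 to 2185 for relAE335Q, and 0 (without relA+ replicate 2; limma, 121 at an unadjusted p under 0.05) to 229 for the response over all times. Late dark against dusk ranged from 455 (without relA+ dusk replicate 2) to 1357 in relA+ and from 1195 (without relAE335Q dusk replicate 2) to 1926 in relAE335Q. The strains at dusk ranged from 145 (without relAE335Q dusk replicate 2) to 1649, the strains in late dark from 976 (without relA+ replicate 1) to 2018, and the difference of late dark responses from 0 (4 settings; limma, 199 to 566 at an unadjusted p under 0.05) to 75.

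The strains at dusk (1536 as reported) gave 94 with median centring, 125 with quantile normalization, 87 with edgeR and TMM, 84 scaled to a common total without the R series and 50 with 1 value per course, median centred. The difference of late dark responses (40) gave 295, 295, 298 and 210 in the first 4 of these, 16 with only the libraries of the contrast, 436 with 1 value per course and 19 with that and median centring. The strains in late dark (1580) gave 989 with a log2 change of at least 1, 162 with 1 value per course and 549 with that and median centring. The response over all times (239) gave 64 with library weights.

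With the replicate block, loci changed over time in relA+ became 1973 (1896 with median centring as well), the response over all times 1532 (883) and the difference of late dark responses 972 (750), and the strains at dusk became 183 with block and median centring. Among the 85 locus results the block alone ended 0 calls (limma) and added 22. These were cikA, gap1 (0.54, adjusted p = 0.0329), gnd (-0.98, adjusted p = 0.000248), opcA (-0.81, adjusted p = 0.000343) and zwf (-0.60, adjusted p = 0.00626) in relA+ late dark, fbp and tal in relAE335Q late dark, hpf, rpaA, rpaB, gnd and tal between the strains at dusk, and hpf, kaiB, gnd and tal between them in late dark. In the difference of late dark responses it added hpf (2.13, adjusted p = 0.00393), kaiA, kaiB, rpaA, fbp (-1.16, adjusted p = 0.00412) and tal. The block assumes that replicate numbers pair libraries. No label says so. All correlations between times lay above 0.1 in relA+ (median 0.463) but not in relAE335Q (median 0.413) or between strains (median 0.222). With medians this close in the strains, a pairing in relAE335Q is not excluded. The correlations also cannot see a shift of a whole library, and replicate 2 had the higher total in every group of both strains. In relA+ late dark the block changed no other call of a named locus or of a list. In relAE335Q late dark the camera calls of the clock list (adjusted p = 0.0524) and of the Rubisco pair (adjusted p = 0.122) were lost with the block.

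For results past the threshold on the deposited scale or in at least 1 of these settings, directions turned as follows, with median centring, quantile normalization, edgeR with TMM and scaling to a common total without the R series in this order. In relAE335Q late dark cikA was at 1.354, 1.267, 1.429 and 1.177 and opcA at 1.091, 1.002, 1.111 and 0.9138, and sasA turned with TMM alone (0.0289). Between the strains at dusk kaiC was at 0.287, 0.2454, 0.3369 and 0.2444, sasA at 0.03961, 0.02806 and 0.09273 (the first 3), kaiB at 0.01636 (TMM alone) and rbcL at 1.265, 1.266, 1.314 and 1.223 (past the threshold with median centring alone). Between the strains in late dark kaiB was at 0.4318, 0.4125, 0.3683 and 0.2603, rpaB at 0.5499, 0.5247, 0.4731 and 0.3751, and rbcS at 0.5716, 0.4708, 0.489 and 0.3957. Median centring with the replicate block and 1 value per course with median centring gave the median centred values again, and the former also took gap1 between the strains in late dark past the threshold at 0.5574. Left-out libraries turned or, on one side, made into calls cikA (-0.5705 and 0.6311), glgP (-1.039 and 0.4819) and gap1 (-0.9417 and 0.5744; in each case without relAE335Q replicate 1 and without replicate 2) between the strains in late dark. Added settings were edgeR, scaling to the total without the R series, block with median centring, 1 value per course and leaving out relAE335Q dark 2 h replicate 2, which moved no count by more than 1.5 times.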

Other observations

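The measures in this part were chosen after the data were seen.

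The B series of tags, whose products were not given in the sources used here, held a larger share of the signal in relA+ than in relAE335Q. At dusk its share was 0.115% and 0.107% in the relA+ libraries and 0.0485% and 0.0541% in relAE335Q, and at 12 h 0.306% and 0.300% against 0.156% and 0.163%. Both relA+ libraries lay above both relAE335Q libraries at 9 of 9 times, with ratios of means between 1.62 at 4 h and 3.18 at 30 min. Of 49 B series loci tested at dusk, 7 were higher in relA+ after median centring and 15 when adjusted over the list alone (median 1.05, camera adjusted p = 1.12e-13, adjusted p = 1.95e-05 with an estimated correlation). In late dark 26 were higher and 2 lower in relA+ after median centring (median 0.73, camera adjusted p = 0.000234, adjusted p = 0.0124 with an estimated correlation). On the deposited scale 0 were higher and 1 lower at dusk and 10 were higher and 8 lower in late dark, and the medians turned to -0.32 and -0.01166.

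The ratio of 12 h to dusk was higher for the summed R series than for the other loci in every time course. In relA+ its signal at 12 h was 1.32 and 1.33 times that at dusk, while that of all other loci was 0.550 and 0.630 times. In relAE335Q the R series was at 0.684 and 0.609 times and the other loci at 0.168 and 0.268 times. One locus, Synpcc7942_R0017, held between 9.15% and 26.1% of the signal of a library. Of 42 R series loci tested 3 were higher and 1 lower in relA+ late dark after median centring (camera adjusted p = 0.339, adjusted p = 0.83 with an estimated correlation) and 3 were higher and 2 lower in relAE335Q late dark (camera adjusted p = 0.0434, adjusted p = 0.652 with an estimated correlation). In the B and R series lists adjusted p-values are over these lists of a contrast.

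Of the loci that changed over time after median centring, 389 of 1492 in relA+ had their highest mean at dusk, 265 at 5 to 30 min, 249 at 1 to 4 h and 589 at 8 or 12 h. In relAE335Q the numbers were 359, 471, 156 and 650 of 1636. On the deposited scale they were 586, 298, 106 and 46 of 1036 in relA+ and 1081, 809, 297 and 17 of 2204 in relAE335Q. The difference between the strains in these numbers was not tested.

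Changes of loci with neighbouring tags were correlated, with a Pearson r across 2600 pairs between 0.375 and 0.441 in the 5 contrasts with a direction (highest r in 1000 permutations 0.071, permutation p = 0.000999, the smallest they can give). Neighbouring loci are thus not independent of each other.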
